A study of Meriones unguiculatus with 18 samples.

How the data were processed

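Liver RNA of male Mongolian gerbils (Meriones unguiculatus) was measured by poly(A) RNA sequencing in 18 libraries, 3 for each combination of diet (normal diet, ND, or high-fat diet, HFD) and time on it (4, 8 or 16 weeks). Per the labels' protocols, libraries were sequenced as paired ends on an Illumina HiSeq instrument, only RNA with an integrity number above 7 was used, and reads of the liver libraries were assembled without a genome by Trinity 2.4.0. Per the same protocols, the longest transcript of each assembled cluster was kept; such a transcript is called a unigene here. Salmon and edgeR are named in the submitters' processing notes, with no version and no role. The treatment protocol speaks of 36 gerbils, 6 per group, and the design text of 18. Whether a library holds 1 animal or a pool, such as 2 animals, is not given in the sources used here. The SD and p-values therefore measure the spread between these libraries, which in a pool is not that between animals. The housing text names both continuous light and a cycle of 12 hours of light and 12 of dark; the hour of tissue collection is not given in the sources used here.

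The deposited values are normalized expression levels made by the authors; the abundance unit before normalization is not given in the sources used here. The values themselves show that the 18 libraries share 1 set of sorted values, with a column sum of 158000 and a highest value of 28800 in each, which is what quantile normalization over all libraries produces. The largest relative gap between sorted libraries was 0.01 over their top 3000 unigenes, and 0 of 153 pairs of libraries held identical values in the same order. The depth of each library is therefore unknown, and no counting interval can be given. The lowest value of each library is shared by many unigenes, and a unigene there is called not detected. After such a normalization a value is set by its rank in the library, so every fold here rests on ranks and not on measured amounts. For the folds the shared values have a further pair of consequences: unigenes at the top of a library take 1 of a few fixed values, and a fold near the bottom depends on the pseudocount.

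Of 13172 unigenes, 3767 carry a gene name in the deposited table, with 3187 distinct names, and 9405 carry none. A table of the gerbil annotation was used for names alone; 3008 of the named unigenes carry a symbol or synonym found in it and 759 do not. Names follow the spelling of the species matched by the authors, so a mouse-style, human-style or plant-style name marks the best match and not the source of the RNA. Closely related copies in 1 family can share reads in a transcript assembly, so values of Cyp2a3, Cyp1a2, Cyp3a11, Cyp4a10 and Ugt2b1 are uncertain as to the copy.

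The planned design was 1 limma fit over all 18 libraries, with diet contrasts at each time, their average, their difference and the change over time in each diet. In the deposited table the 6 libraries of 8 weeks do not follow the other 12 unigene by unigene, so gene names were used with 4 and 16 weeks alone, and the fit reported holds those 12 libraries. The averaged contrast covers 2 times in place of 3, and the 8-week libraries had a fit of their own with no gene names. This change was made after seeing the data, and the planned fit was kept as an alternative. In it the difference between times and the changes over time were F tests over 8 and 16 weeks. Each unigene's mean and spread there take in the 8-week values, which do not follow the other times. Its counts and lost calls are therefore not a like comparison.

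In each fit log2(value + 1) was modelled by limma 3.58.1 in R 4.3.3 with an intensity trend of the variance, over unigenes with a mean of at least 1 (9487 in the 12-library fit and 8910 in the 8-week fit). Unigenes with a Benjamini-Hochberg adjusted p under 0.05 were called. Folds are on the log2(value + 1) scale, which understates the change of low unigenes, and no filter other than the mean was applied. Group values are given as mean ± SD over 3 libraries, and folds with their standard error (SE). Gene lists (39) were written before the data were examined, as were the tests, the rule for named genes and those alternatives not marked below as later additions. A list was tested with limma's camera, at a preset correlation of 0.01 between genes, where it had at least 5 members in the fit. This left 21 lists at 4 and 16 weeks. Counts of list members below are of members in the fit, often a small part of the list. These were 8 of 24 stellate, 9 of 47 fibrosis, 8 of 30 macrophage and 5 of 28 xenobiotic genes. Lists can share members, as Col1a1 is on both the stellate and the fibrosis list. Camera was repeated with the correlation estimated for each list, and fry, a test of whether a list's own members move one way, was run beside it.

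Genes were named by a fixed rule: for each diet contrast the 12 largest rises and the 12 largest falls among called unigenes with a name, whose 3 HFD values lay all on one side of the 3 ND values and whose higher group mean was at least 5. For the difference between times and for each change over time the rule took the 6 names of smallest p, for each list up to 4 members of smallest p, and in addition a panel of 30 genes whether called or not. The averaged contrast used the same rule without the condition on overlap. Because many of the largest falls were in unigenes found in few libraries, the rule was run a second time over the unigenes detected in all 12 libraries, a step chosen after seeing the data. Some genes that the rule or a list takes in are not reported here.

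The titles give each group the replicate numbers 1 to 3. Deviations from the group means were correlated between libraries of the same number. Between 4 and 16 weeks in HFD these were 0.40, 0.18 and 0.12, all above 0.1. The numbers were therefore taken as possible pairs there when the replicate block and the splits were read. The fits reported hold no term for the number, so their tests of time in HFD and of the interaction are unpaired. Between diets and within ND the numbers were not taken as possible pairs. Libraries of different numbers were not compared in this way. The HFD libraries numbered 1 also differed from the others in which unigenes were detected. Pearson's r of log values with HFD 16W 2 was 0.69 for HFD 4W 2 and 0.68 for HFD 4W 3. With HFD 16W 3 it was 0.75 for each, so a pairing is not shown.

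Alternatives were a pseudocount of 0.1 or 5, a mean of at least 5 or no filter, median-ratio rescaling, values summed by gene symbol, array weights, a replicate block, separate fits per time, the planned 18-library fit and leaving out each library in turn. Further alternatives, chosen after seeing the data, were unigenes detected in all 12 libraries, lowest values set to 0, a term for the library set, the HFD libraries numbered 1 left out, and unigenes with a gerbil symbol alone. The model fit and the calling were tested on simulated log values with 100 unigenes changed at each fold size. Noise was normal and drawn independently at each unigene's residual SD. Normalization, lowest values, the filter, library sets and the averaged contrast were not part of this test. Far fewer unigenes were changed than were called in most comparisons, so the recovered shares do not measure the power of the real fits. At a log2 change of 1 the diet contrast recovered 15% of them at 4 weeks and 14% at 16 weeks, with 47% at each time for a log2 change of 2, and with 1 and 4 false calls among 9487. The difference between times recovered 2% and 21%, with 2 false calls, and the 8-week fit 0% and 1%, with 0 false calls among 8910. The change over time recovered 16% and 41% in ND and 16% and 47% in HFD, with 5 and 4 false calls among 9487. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.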

Results

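Liver gene expression was measured in 18 libraries of male Mongolian gerbils, a desert rodent used as a model of fatty liver disease, fed a normal diet (ND) or a high-fat diet (HFD) for 4, 8 or 16 weeks, with 3 libraries in each of the 6 groups. In the HFD, 80.5% was ordinary feed, and the rest was egg yolk powder (10%), lard (7%), cholesterol (2%) and bile salt (0.5%). The table held 13172 assembled transcripts (unigenes), of which 3767 had a gene name, and 3646 were detected in all 12 libraries of 4 and 16 weeks. Sequencing depth was unknown, because all libraries had been brought to the same set of sorted values. Pearson's r of log values across unigenes, which are not independent replicates, was 0.77 to 0.86 for the 12 pairs of libraries of 1 group at 4 and 16 weeks. For the 18 pairs of different diet at the same time it was 0.52 to 0.74.

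Libraries of 8 weeks had their own order of unigenes. Their r with the libraries of 4 and 16 weeks was 0.00 to 0.03 (72 pairs, median 0.02), whereas it was 0.70 to 0.79 between 8-week libraries of the same group (6 pairs). The unigene named ALB, for serum albumin, the main protein secreted by hepatocytes, had values of 8090 to 28800 at 4 weeks and 5760 to 28800 at 16 weeks, but 0 to 3.14 at 8 weeks. Of the 200 highest unigenes of a library, 86.5% to 92.0% had a name at 4 and 16 weeks and 26% to 31% at 8 weeks. Gene names were therefore used with 4 and 16 weeks alone.

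**Figure D1:**
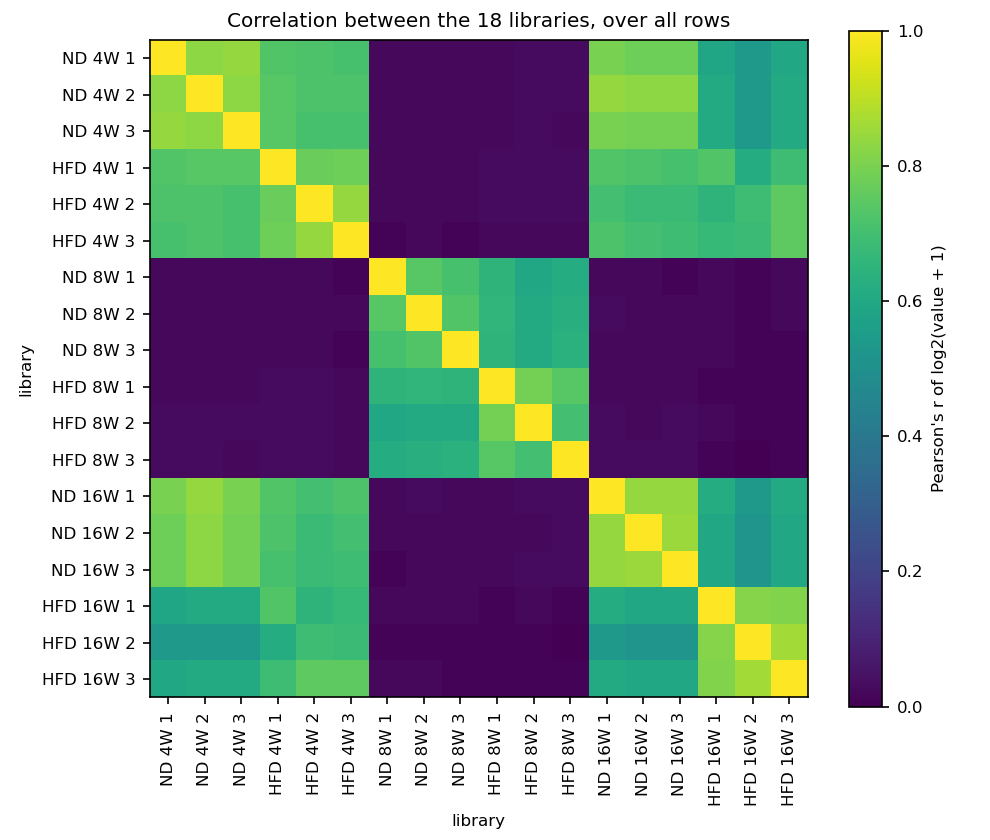
Heat map of Pearson's r between the 18 libraries (rows and columns, grouped by diet and time), computed across unigenes on log2(value + 1). The 8-week libraries correlate with each other at 0.60 to 0.79 but with the other 12 libraries at 0.00 to 0.03.

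The 12 libraries of 4 and 16 weeks fell into 3 sets by which unigenes were detected, and the sets ran with diet. Unigenes with a ribosomal or mitochondrial name in fruit fly spelling (33) were detected in 0 ND libraries and in 0 HFD libraries numbered 1. In each of the other 4 HFD libraries 32 or 33 of them were detected. Other fly names were not counted. Of 14 unigenes with a plant locus name, 9 or 10 were detected in each ND library, 0 in the HFD libraries numbered 1 and 4 in the other HFD libraries. Among named unigenes seen in ND libraries alone (90), 76.7% had a name outside the gerbil annotation, compared with 14.1% of 2198 named unigenes detected in all 12 libraries (Fisher's exact test, p = 3.8e-38). ND libraries had 3910 to 5273 unigenes at the lowest value and HFD libraries 2053 to 3012. No set held both diets, so every comparison of HFD with ND is also a comparison of library sets, and the 2 cannot be told apart; changes over time lie within sets.

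**Figure D2:**
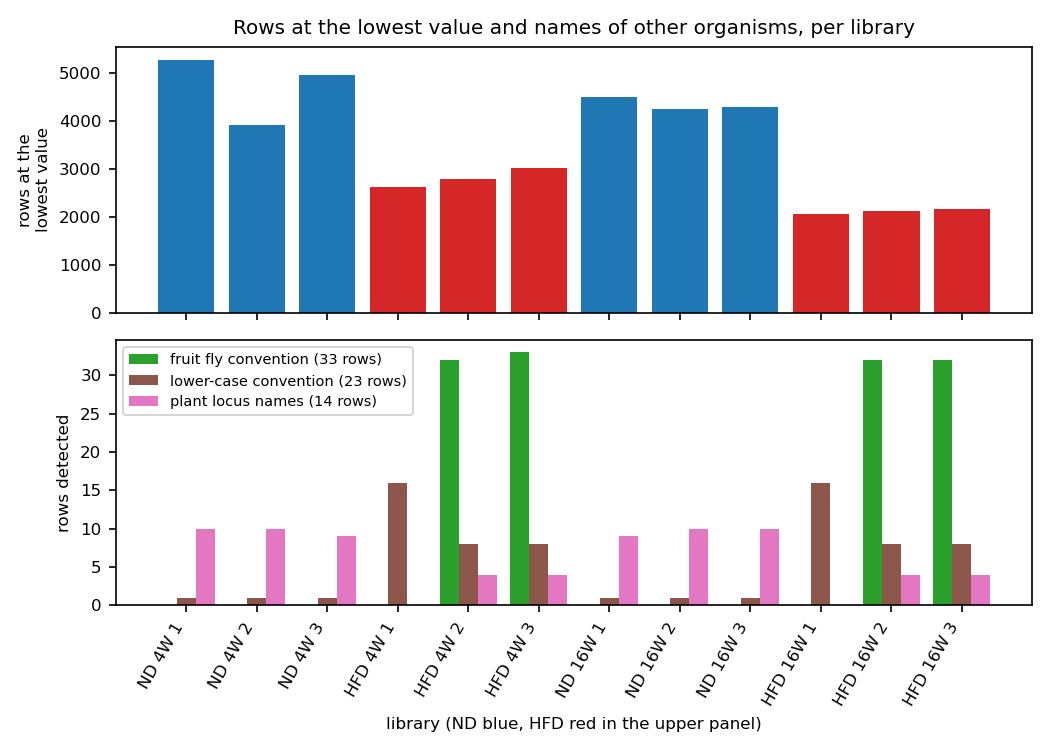
Upper bars, unigenes at the lowest value in each of the 12 libraries of 4 and 16 weeks. Lower bars, unigenes detected per library among ribosomal or mitochondrial names in fruit fly spelling (33) or lower case (23), and plant locus names (14). The names in fly spelling appear in 4 HFD libraries and in no ND library.

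At 4 weeks, HFD was compared with ND to ask which liver genes had changed early on the diet, and the named genes of macrophages and of collagen matrix were higher on HFD. Cd5l (TRINITY_DN31636_c0_g1), a protein secreted by tissue macrophages, rose from 5.49 ± 4.43 in ND to 51.7 ± 12.5 in HFD (mean ± SD, n = 3 each; log2 fold change 3.38, SE 0.63, limma Benjamini-Hochberg adjusted p = 0.00508). Col1a1 (TRINITY_DN32772_c0_g1), a chain of type I collagen, rose from 0.960 ± 0.0511 to 19.4 ± 5.80 (log2 fold change 3.34, SE 0.32, limma adjusted p = 0.000107). Gpnmb (TRINITY_DN35089_c2_g2), a lysosomal glycoprotein of macrophages, rose from 1.82 ± 0.54 to 20.5 ± 8.68, and Cd68 (TRINITY_DN29163_c0_g1), a lysosomal macrophage marker, from 8.89 ± 0.158 to 45.0 ± 9.64. Slc11a1, a metal transporter of the phagosome, and Cd53, a leukocyte membrane protein, rose by log2 2.34 and 2.14. The beta-tubulin TUBB2B rose by log2 2.95, and Hmox1, the enzyme that breaks down haem, rose from 13.5 ± 0.583 to 43.0 ± 4.81.

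By list, 4 of 8 macrophage and monocyte markers rose at 4 weeks and none fell; 6 rose when adjusted over the list alone. The 4 were Cd5l, Gpnmb (log2 2.88), Cd68 (2.19) and Itgax (1.33), and the median of the list was 1.51 (camera adjusted p = 0.00436 and adjusted p = 0.68 with an estimated correlation). Of 9 fibrosis and extracellular matrix genes, 4 rose and none fell, also 4 when adjusted over the list alone. They were Col1a1, the collagen chaperone Serpinh1 (log2 1.62), Col5a2 (1.28) and the elastin gene Eln (1.15), with a median of 1.03 (camera adjusted p = 0.0187 and adjusted p = 0.68 with an estimated correlation). This list was no longer called without library ND 4W 2 (camera adjusted p = 0.051) or after median-ratio rescaling (adjusted p = 0.0652). Eln was no longer called in the 18-library fit (limma adjusted p = 0.165) or in a fit of 4 weeks alone (adjusted p = 0.0864). Calls lost in the 18-library fit, here and below, may reflect the 8-week values that it takes in. Of 8 stellate cell markers 3 rose, 4 when adjusted over the list alone, among them Des, the muscle-type filament desmin (from 6.25 ± 0.798 to 28.8 ± 6.14), but the list was not called (camera adjusted p = 0.0815). By fry the macrophage, fibrosis and stellate lists had an adjusted p of 0.00432, 0.00471 and 0.0329.

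Genes of sterol synthesis were lower on HFD at 4 weeks. All 3 measured of 20 on the cholesterol synthesis list fell, too few for a list test. Cyp51a1, the lanosterol demethylase, fell from 60.7 ± 14.3 to 14.3 ± 1.05 (n = 3 each; log2 fold change -1.99, SE 0.30, limma adjusted p = 0.0014), and Ebp, the sterol isomerase, from 71.1 ± 13.8 to 32.8 ± 6.15, a call lost in the 18-library fit (limma adjusted p = 0.148). Lss, the lanosterol synthase, had a log2 fold change of -1.27 (limma adjusted p = 0.016), which was not called without ND 4W 3 (adjusted p = 0.0553) or HFD 4W 2 (adjusted p = 0.0568). Insig1, the sterol-regulated anchor of SREBP processing, fell from 57.3 ± 16.2 to 16.2 ± 3.35 (log2 -1.74, SE 0.22, limma adjusted p = 0.000534). Npc1l1, a cholesterol transporter and the other of 2 measured targets of SREBP2 outside the synthesis pathway, was not called (log2 0.73, limma adjusted p = 0.415), and 2 members were too few for a list test. Of 9 respiratory chain genes 3 fell, 4 when adjusted over the list alone, and none rose. Ndufb5 of complex I had a log2 fold change of -1.28 (limma adjusted p = 0.000355, and 0.105 in the 18-library fit). The list was not called by camera (adjusted p = 0.0597), and its fry adjusted p was 0.011. The others of the 3, COX6C and COX7A2, were detected in all 6 ND libraries of 4 and 16 weeks but in 2 and 1 of the 6 HFD libraries. COX7A2 was no longer called at 4 weeks without ND 4W 1 (limma adjusted p = 0.0627), HFD 4W 2 (0.0533) or HFD 4W 3 (0.0579). Among unigenes detected in all 12 libraries, the 12 largest named falls held the mitochondrial genes Atp5i, Ndufs6, ATP5G1 and Cmc2. Their log2 fold changes were -1.93, -1.75, -1.62 and -1.51, and that of Acsm1, a mitochondrial acyl-CoA synthetase, was -1.65. These genes were picked for the size of their falls and were not tested as a set.

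The 12 largest named falls at 4 weeks by the rule were all in unigenes detected in at most 2 of the 6 HFD libraries. They held the ribosomal protein names RPL38 and RPS15, the MHC class I names HLA-E and HLA-B, and the plant gene names TIC32 and RBG7, which were at the lowest value in every HFD library. RPL38 fell from 21.3 ± 4.88 to 0.688 ± 1.19. In all, 1149 of 9487 unigenes were called at 4 weeks (limma, Benjamini-Hochberg), 464 higher and 685 lower on HFD. With values summed by symbol 306 were higher and 445 lower, and with gerbil symbols alone 274 and 351. The larger number of falls was reversed with a term for the library set within HFD (822 higher, 755 lower), without the HFD libraries numbered 1 (655 and 598) and after median-ratio rescaling (600 and 504). Rescaling moved the median log2 fold change over all unigenes from -0.03 to 0.09 (at 16 weeks from -0.12 to 0.01, at 8 weeks from 0.03 to 0.17). Of the 685 lower unigenes, 191 were at the lowest value in all HFD libraries. Among the 3377 tested unigenes detected in all 12 libraries, 827 were called. The count fell to 710 without HFD 4W 3 and 747 without ND 4W 1, and was 654 in the planned 18-library fit.

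At 16 weeks, the same comparison asked which genes differed after long feeding. Lists of stellate cell, fibrosis and macrophage genes were called as higher on HFD. Those of xenobiotic metabolism, of the urea cycle and amino acid breakdown, of glycolysis and gluconeogenesis and of the respiratory chain were called as lower. None of these 7 lists was called with an estimated correlation. By fry, which does not compare a list with the other genes, all had an adjusted p of at most 0.00266. Col1a1 rose from 0.784 ± 0.305 to 354 ± 190 (n = 3 each; log2 fold change 7.52, SE 0.32, limma adjusted p = 1.47e-07). Gpnmb rose from 6.67 ± 4.53 to 1436 ± 150 (log2 7.81, SE 0.47, limma adjusted p = 8.19e-07). Ckb, the brain-type creatine kinase, rose from 4.33 ± 1.99 to 334.6 ± 50.8, and Sfrp1, a secreted antagonist of Wnt signalling, from 1.66 ± 0.506 to 166.4 ± 90.1. Clu, which encodes the secreted chaperone clusterin, rose from 778 ± 482 to 21870 ± 11900 (log2 4.76, SE 0.57, limma adjusted p = 9.67e-05) and was the highest unigene in 2 of the 3 HFD libraries, at ranks whose values the normalization fixes. Largest among the named falls was Cyp2a3, a drug-metabolising cytochrome, from 1172 ± 157 to 22.6 ± 17.1 (log2 -6.04, SE 0.62, limma adjusted p = 3.21e-05). Leap2, a liver peptide that opposes ghrelin, fell with a log2 fold change of -4.50, and Abat, which breaks down GABA, -3.79.

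**Figure D3:**
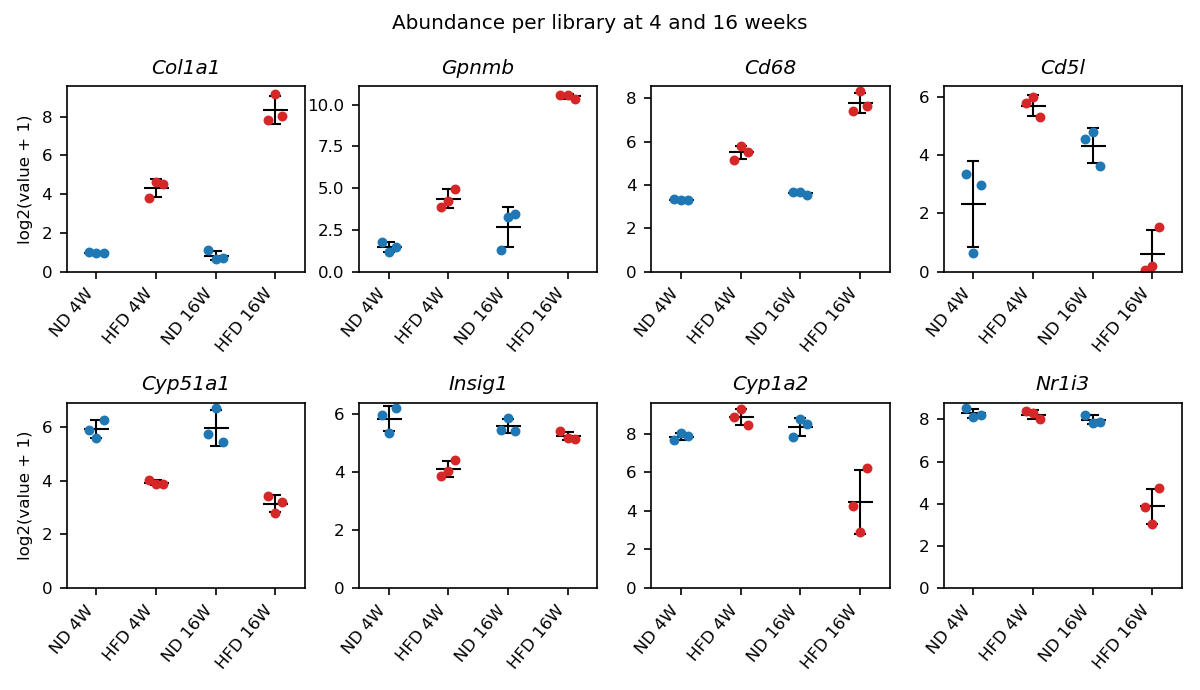
Values of 8 genes on a log2(value + 1) axis in ND (blue) and HFD (red) at 4 and 16 weeks; points are libraries, and bars give the mean and SD of 3 libraries. Col1a1, Gpnmb and Cd68 are higher on HFD at both times, Cd5l is higher at 4 and lower at 16 weeks, and Cyp1a2 and Nr1i3 are lower at 16 weeks.

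All 8 measured of 24 stellate cell and myofibroblast markers on the list rose at 16 weeks. Their median log2 fold change was 3.42 (camera adjusted p = 0.00146 and adjusted p = 0.61 with an estimated correlation). They included Des (from 8.78 ± 1.37 to 450 ± 175), the matrix proteoglycan Lum (log2 4.36) and the surface protein Thy1 (3.61). Of 9 fibrosis and extracellular matrix genes 7 rose, among them Col1a1, Eln (4.12), Serpinh1 (3.87) and Col5a2 (3.67), and 2 were not called (median 3.67, camera adjusted p = 0.00146 and adjusted p = 0.61 with an estimated correlation). Of 8 macrophage markers 6 rose and 1 fell. Those that rose included Cd68 (from 11.3 ± 0.555 to 229 ± 78.9) and Itgax (log2 3.99), an integrin of macrophages and dendritic cells, and the 1 that fell was Cd5l (from 20.1 ± 7.86 to 0.689 ± 1.04; log2 -3.73, SE 0.63, limma adjusted p = 0.00091). The list was called (median 2.44, camera adjusted p = 0.0281 and adjusted p = 0.61 with an estimated correlation), but not after median-ratio rescaling (adjusted p = 0.0503).

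Of 5 genes of xenobiotic metabolism 4 fell at 16 weeks, with a median log2 fold change of -3.02 (camera adjusted p = 0.0281 and adjusted p = 0.61 with an estimated correlation). Nr1i3, the nuclear receptor CAR that induces drug-metabolising enzymes, fell from 255 ± 37.8 to 15.4 ± 9.21 (log2 -4.11, SE 0.33, limma adjusted p = 5.89e-06). Cyp1a2 fell from 337 ± 104 to 32.4 ± 35.2, and Cyp3a11 and Ugt2b1 had log2 fold changes of -3.02 and -2.46. Of 6 genes of the urea cycle and amino acid breakdown 5 fell (median -1.85, camera adjusted p = 0.0281 and adjusted p = 0.64 with an estimated correlation), among them Hpd of tyrosine breakdown (log2 -2.86), Ass1 of the urea cycle (-2.50) and Tdo2 of tryptophan breakdown (-2.36). Of 8 genes of glycolysis and gluconeogenesis 4 fell, 5 when adjusted over the list alone (median -1.83, camera adjusted p = 0.0281 and adjusted p = 0.61 with an estimated correlation). Those that fell included the liver glycogen synthase Gys2 (log2 -3.41), the glucose transporter Slc2a2 (-2.34) and Fbp1 of gluconeogenesis (-2.33), and this list was not called with values summed by symbol (adjusted p = 0.0518). Of 9 respiratory chain genes 5 fell, among them Ndufb5 with a log2 fold change of -1.67 (median -0.84, camera adjusted p = 0.0281 and adjusted p = 0.64 with an estimated correlation), and the list was not called at a mean of at least 5 (adjusted p = 0.0596). COX6C and COX7A2, detected in few HFD libraries, were another pair of the 5.

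The sterol genes stayed lower at 16 weeks, with log2 fold changes of -2.99 for Ebp, -2.82 for Cyp51a1 and -2.29 for Lss, whereas Insig1 did not pass (46.8 ± 8.01 in ND and 36.6 ± 3.69 in HFD, limma adjusted p = 0.252). Npc1l1 was called as higher at 16 weeks (from 0.404 ± 0.603 to 3.77 ± 2.64, log2 1.71, SE 0.52, limma adjusted p = 0.0249), but was detected in 1 of the 6 ND libraries. This call was lost without ND 16W 1 (limma adjusted p = 0.0741) or 2 (0.0784) and with a pseudocount of 0.1 (0.0501). Of the fixed panel of 30 genes 6 could be tested, and the others are not analysed here. Besides Col1a1, Gpnmb and Cd68, Mki67, a proliferation marker, rose at 16 weeks (log2 1.70, SE 0.26, limma adjusted p = 0.000422) but not at 4 weeks (0.38 and adjusted p = 0.375). Of 6 cell cycle genes, Mki67 among them, 2 rose and 2 fell at 16 weeks (camera adjusted p = 0.962), and TOP2A, a topoisomerase of dividing cells, was at the lowest value in all HFD libraries. Fasn, the fatty acid synthase, had log2 fold changes of -0.10 and 0.09 (adjusted p = 0.897 and 0.866, limma), and Afp, the fetal liver protein raised in carcinoma, of -0.95 and -0.09 (adjusted p = 0.107 and 0.872), none of which passed. Of 7 genes raised in hepatocellular carcinoma 3 rose and 1 fell at 16 weeks, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.514), and of 7 hepatocyte markers 2 fell and none rose (camera adjusted p = 0.389). By fry, which does not compare a list with the other genes, the adjusted p of these 2 lists was 0.00954 and 0.0891. That of the cell cycle list was 0.192.

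By camera 7 of 21 lists were called at 16 weeks, none of them with an estimated correlation. Of 10 splits of the 16-week libraries 4, the real one included, called as many lists or more. In all, 3340 of 9487 unigenes were called at 16 weeks (limma), 1451 higher and 1889 lower. The larger number of falls was reversed after median-ratio rescaling (1761 higher, 1737 lower), with no filter (2054 and 2014), with values summed by symbol (835 and 718) and with gerbil symbols alone (760 and 575). Among tested unigenes detected in all 12 libraries the count was 1908. At both times the diets also differed in library set, and the sets carry names outside the gerbil annotation: 33.3% of the named falls at 16 weeks and 34.8% at 4 weeks had such a name, compared with 9.65% and 16.0% of the named rises. Such a name need not mark reads of another organism. Cyp2a3 and Cyp1a2 among the falls, and Ccl21a and TUBB2B among the rises, had one and were detected in all 12 libraries. The shares therefore do not measure such reads.

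**Figure D4:**
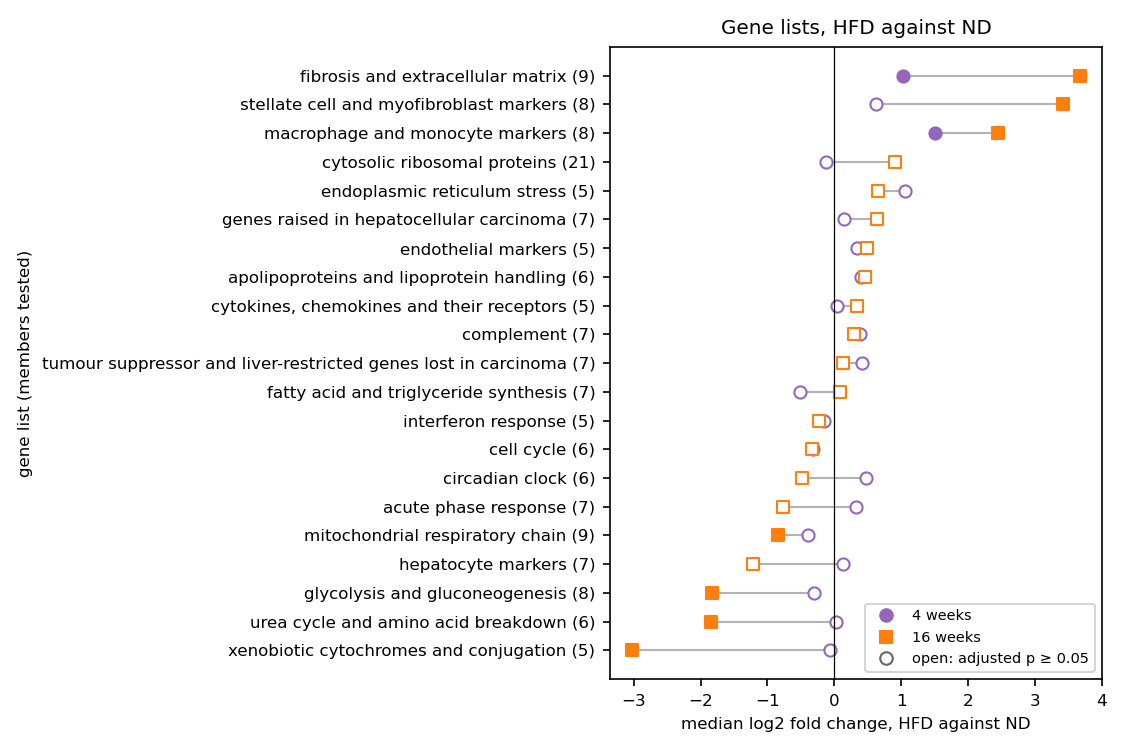
Median log2 fold change of HFD against ND per gene list at 4 weeks (circles) and 16 weeks (squares), with the number of tested members in brackets; filled symbols have a camera adjusted p under 0.05. Fibrosis and macrophage lists are filled at both times. Further lists (5) are filled at 16 weeks alone, of which stellate markers lie highest (3.42) and xenobiotic genes lowest (-3.02). No list was called at either time with an estimated correlation.

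Averaged over 4 and 16 weeks, genes of matrix and macrophages were among the largest rises. Col1a1 rose by log2 5.43 (SE 0.23, limma adjusted p = 5.5e-08, n = 6 each), Gpnmb by 5.34 and Des by 3.74, and the liver genes Cyp2a3 and Leap2 had log2 fold changes of -3.60 and -3.10. Fibrosis genes and stellate markers were called as higher (camera adjusted p = 0.00393 and adjusted p = 0.69 with an estimated correlation), as were macrophage markers (adjusted p = 0.0121; 0.69 as adjusted p with an estimated correlation). Respiratory chain genes were called as lower (camera adjusted p = 0.0186 and adjusted p = 0.88 with an estimated correlation), but not in the planned fit (adjusted p = 0.213), with gerbil symbols alone (0.0676) or at a mean of at least 5 (0.064). Of 9487 unigenes 3652 were called, 1656 higher and 1996 lower. The larger number of falls was reversed after median-ratio rescaling (2058 higher, 1692 lower), with values summed by symbol (842 and 781) and with gerbil symbols alone (771 and 637).

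The calls of 4 and 16 weeks, which share no library, overlapped: 283 unigenes were higher at both times where independent lists would share 71 (Fisher's exact test, p = 7.52e-120), and 494 were lower at both where 136 would be shared (p = 1.27e-211). In opposite directions, 18 were higher at 4 and lower at 16 weeks, Cd5l among them, and 6 were lower at 4 and higher at 16 weeks. In the fit of both times each unigene has 1 variance estimate for both contrasts, which by itself can raise the overlap. Fisher's test also takes unigenes as independent, so its p-values overstate the evidence. With a separate fit for each time, which shares no variance estimate, 180 higher (41.8 by independence) and 341 lower (106) were shared. Across the 9487 unigenes, which are not independent, log2 fold changes of both times had r = 0.506 and rho = 0.500. Both times carry the same difference in library set.

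Whether the diet effect differed between 4 and 16 weeks was tested as an interaction, in which stellate cell and fibrosis genes were among those with higher values at 16 weeks, and genes of xenobiotic metabolism, of the urea cycle and amino acid breakdown and of glycolysis and gluconeogenesis among those with lower values. Ccl21a, a lymphoid chemokine, was 6.46 ± 2.09 in ND and 7.94 ± 1.88 in HFD at 4 weeks, and 4.67 ± 0.954 and 197.9 ± 25.1 at 16 weeks (difference of log2 fold changes 4.86, SE 0.33, limma adjusted p = 8.62e-05). FHL2, a LIM-domain protein of muscle and fibroblasts, gained 3.52 (SE 0.27, limma adjusted p = 0.000126), the matrix protein Fndc1 4.55, and Ezr, which ties the membrane to actin, 2.98. Nr1i3 differed by -4.05 (SE 0.47, limma adjusted p = 0.00086), Cyp1a2 by -4.90 and Gys2 by -2.67. Cd5l, higher on HFD at 4 and lower at 16 weeks, differed by -7.11 (limma adjusted p = 0.00142). Insig1, lower at 4 weeks alone, differed by 1.40 (limma adjusted p = 0.0158).

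By list, 6 of 8 stellate markers had a larger diet effect at 16 weeks, 8 when adjusted over the list alone (median difference 2.57), as had 7 of 9 fibrosis genes (2.39, camera adjusted p = 0.00116 for each list and adjusted p = 0.36 with an estimated correlation). Lower were 3 of 5 xenobiotic genes (-3.34, camera adjusted p = 0.00301), 2 of 6 genes of the urea cycle and amino acids, 4 when adjusted over the list alone (-1.36 and adjusted p = 0.00301), and 3 of 8 genes of glycolysis and gluconeogenesis, 4 over the list alone (-1.73 and adjusted p = 0.00381). Of 6 clock genes 2 were lower, Per3 (-2.09) and Per2 (-1.47) (list median -0.55, camera adjusted p = 0.0255), and of 21 ribosomal protein genes 10 were higher, RPLP0 by 1.55 (median 0.72 and adjusted p = 0.0393). With an estimated correlation these 5 lists had an adjusted p of 0.36, 0.4, 0.36, 0.4 and 0.46. Of the 21 ribosomal protein genes, 11 had a unigene detected in all 12 libraries (camera adjusted p = 0.000349 over such unigenes alone, at the preset correlation). Names were matched to lists without regard to letter case, so a ribosomal unigene in fly or lower-case spelling may stand for the gerbil gene. Of 9487 unigenes 959 were called, 522 with a higher and 437 with a lower value at 16 weeks. The split was 511 and 241 with values summed by symbol, 479 and 196 with gerbil symbols alone and 547 and 485 after median-ratio rescaling. The count was 590 without HFD 16W 2 and 455 without the HFD libraries numbered 1. The planned 18-library fit called 2179, by an F test that takes in the 8-week values.

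Change over time within each diet was tested between 4 and 16 weeks. In HFD, Ccl21a rose by log2 4.49 (limma adjusted p = 4.45e-06), Fndc1 by 4.61, Des by 3.87 and Sdcbp, the adaptor syntenin, by 2.50, from 44.4 ± 5.20 to 256 ± 40.5. Fibrosis genes (7 of 9, median 2.43) and stellate markers (7 of 8, 2.50) rose (camera adjusted p = 0.00103 each and adjusted p = 0.46 with an estimated correlation). Xenobiotic genes fell (4 of 5, median -3.22, camera adjusted p = 0.00695), as did urea cycle and amino acid genes (3 of 6, 4 over the list alone, -1.17; 0.0183) and genes of glycolysis and gluconeogenesis (3 of 8, -0.54; 0.0308), at an adjusted p of 0.46, 0.51 and 0.46 with an estimated correlation. Of 9487 unigenes 1610 were called in HFD, 872 higher and 738 lower. The split was 681 and 370 with values summed by symbol, 646 and 312 with gerbil symbols alone and 1044 and 734 after median-ratio rescaling. Falls outnumbered rises with a pseudocount of 0.1 (789 higher, 872 lower), at a mean of at least 5 (433 and 481) and among unigenes detected in all 12 libraries (699 and 761). The count was 981 without HFD 16W 2 and 931 without the HFD libraries numbered 1.

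In ND, 36 unigenes were called, 20 higher and 16 lower at 16 weeks (limma; 1549 at an unadjusted p under 0.05). After median-ratio rescaling 34 were called, 23 higher and 11 lower, with values summed by symbol 45 higher and 41 lower, and with gerbil symbols alone 64 and 59. Falls outnumbered rises at a mean of at least 5 (54 higher, 71 lower) and among unigenes detected in all 12 libraries (61 and 89). They also did with a pseudocount of 0.1 (24 and 32) and with no filter (6 and 8). Calls of the F test in the planned 18-library fit split into 1929 higher and 2472 lower at 16 than at 4 weeks. That test takes in the 8-week values, so these are not calls of a change from 4 to 16 weeks. Among the named ones CORO1B, an actin-binding coronin, rose from 10.3 ± 2.27 to 22.4 ± 1.30 (log2 1.06, SE 0.18, limma adjusted p = 0.0457). CORO1B was not called without ND 4W 1 (limma adjusted p = 0.118) or 3 (0.109), ND 16W 1 (0.0524), 2 (0.106) or 3 (0.134), HFD 4W 2 (0.0552) or 3 (0.0514), or HFD 16W 1 (0.0575), 2 (0.0501) or 3 (0.0588). The total of ND calls was 0 without ND 16W 2, 1 without ND 4W 1, 233 without ND 4W 2 and 60 without ND 16W 1. It was 21 without ND 4W 3, 5 without ND 16W 3, 17 and 10 without HFD 4W 1 and 3, and 12, 20 and 7 without HFD 16W 1, 2 and 3. The clock list was called as higher (median 0.55, camera adjusted p = 0.0204 and adjusted p = 0.86 with an estimated correlation), with 0 of 6 members called over all genes and 3 over the list alone.

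At 8 weeks, HFD was compared with ND within the 6 libraries of that time, without gene names. TRINITY_DN35731_c2_g1 rose from 1.74 ± 0.423 to 269 ± 28.4 (n = 3 each; log2 fold change 6.63, SE 0.20, limma adjusted p = 8.04e-05) and TRINITY_DN33456_c0_g1 from 9.35 ± 2.57 to 324 ± 122 (log2 4.94, SE 0.30, limma adjusted p = 0.00252). TRINITY_DN35044_c0_g2 fell from 50.9 ± 8.63 to 2.22 ± 0.99 (log2 -4.05, limma adjusted p = 0.0027), and TRINITY_DN36425_c0_g1, at the highest value of 28800 in every ND library, to 2560 ± 1680 in HFD. Of 8910 unigenes 522 were called, 279 higher and 243 lower (limma; 1933 at an unadjusted p under 0.05), and 326 higher and 199 lower after median-ratio rescaling. Without ND 3 falls outnumbered rises (107 higher, 167 lower). Every library mattered to this count: it was 80, 108 and 274 without ND 1, 2 and 3, and 56, 124 and 134 without HFD 1, 2 and 3. In the planned 18-library fit it was 1204.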

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

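The tests of explanations and the grouping of splits by whether they mix the HFD libraries were chosen after the result was seen; the test of a difference between times and the splits themselves were planned.

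The interaction test called 959 unigenes whose diet effect differed between 4 and 16 weeks, and the genes named here are among them, each with its log2 fold change at 16 weeks minus that at 4 weeks (limma, Benjamini-Hochberg). Matrix and stellate genes had positive differences, of 4.55 for Fndc1, 4.29 for Lum, 4.18 for Col1a1, 3.45 for Des, 2.97 for Eln, 2.93 for Thy1, 2.39 for Col5a2 and 2.25 for Serpinh1. Genes of macrophages and other leukocytes had differences of 4.93 for Gpnmb, 2.66 for Itgax, 1.98 for Cd68, 1.87 for Cd53 and 1.02 for Slc11a1, but -7.11 for Cd5l. Of 8 macrophage markers 3 were called with a positive and 1 with a negative difference, 4 and 1 when adjusted over the list alone. The macrophage list was not called (camera adjusted p = 0.134 and adjusted p = 0.5 with an estimated correlation). Other genes with positive differences were Ccl21a (4.86), Sfrp1 (4.47), Ckb (4.26), Clu (3.71), FHL2 (3.52), Ezr (2.98), Sdcbp (2.26), TUBB2B (2.09), RPLP0 (1.55), Insig1 (1.40), Gpx4 (1.40) and Mki67 (1.32). Genes of the stress response had 2.40 for HSPB1, 2.24 for SRXN1, 1.65 for Hsp90aa1 and 1.44 for Hspa8. Drug-metabolism genes had negative differences, of -4.90 for Cyp1a2, -4.88 for Cyp2a3, -4.05 for Nr1i3 and -3.34 for Ugt2b1. Genes of sugar, amino acid and fat metabolism had -3.40 for Cyp4a10, -3.30 for Mlxipl, -2.76 for Abat, -2.67 for Gys2, -2.58 for Hpd, -2.50 for Slc2a2, -2.02 for Acsm1, -1.89 for Ebp, -1.76 for ACOT1 and -1.38 for Glud1. Of the clock genes Per3 had -2.09 and Per2 -1.47.

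By list, the median differences were 2.57 for stellate markers, 2.39 for fibrosis genes, 0.72 for ribosomal proteins, -0.55 for clock genes, -1.36 for urea cycle and amino acid genes, -1.73 for glycolysis and gluconeogenesis, and -3.34 for xenobiotic genes. Of 100 splits of the time labels within diets, 2 gave a count as large as the real one (959, highest other 1258). Such splits also break up the change over time within each diet, so for a differing diet effect they leave open whether chance can be excluded. The counts followed the structure of the HFD libraries: the 13 other splits that kept the HFD libraries of 4 and 16 weeks apart called 586 to 1258, whatever the ND labels, and the 86 that mixed them called 0 to 2. Of these 86, the 31 that part every pair of same-numbered HFD libraries called 0 to 1. The highest of the 13 lay above the real count and the others below it, so the real count is not the highest of its kind. With fewer libraries the real grouping gave 590 (without HFD 16W 2) and 455 (without the HFD libraries numbered 1). Those counts cannot be set beside splits of all 12 libraries.

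Over the 3377 tested unigenes detected in all 12 libraries, the median absolute log2 fold change between diets was 0.38 at 4 weeks and 0.73 at 16 weeks. Some differences between diets were smaller or opposite at 16 weeks, as for Insig1 and Cd5l, and library set ran with diet at both times. Unigenes found in some libraries alone are argued against as the whole cause of the differing diet effects. The interaction called 992 of these 3377 unigenes. A loss of hepatocytes that left the proportions of the other cell types unchanged would raise their markers alike. At 16 weeks stellate markers (mean log2 fold change 3.54, SD 2.26, 8 genes) lay 3.19 above endothelial markers (0.34, SD 0.64, 5 genes). A 2-sided exact permutation test gave p = 0.0117 (1287 arrangements), with genes and not libraries as its units. Growth of a single cell type would also lower the share of hepatocytes, so a change in cell composition is not excluded. More activated stellate cells or more matrix expression per cell after longer feeding remain open as hypotheses, and neither was tested apart from the other. A difference between library sets that changed over time was not tested.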

How the results depend on the processing

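The 12-library and 8-week fits and the alternatives on detection, lowest values, library sets and gerbil symbols were chosen after the data were seen; the other alternatives were planned. Of 158 counts under alternatives other than leaving out a library, 116 lay within 1.5 times the value reported. The 158 take in the list counts at 8 weeks, where names do not pair with values. There every count but that of fry was 0, like the value reported, so they say little about stability. Depth is unknown, so what it limits could not be measured. Where a count differed by more, fewer unigenes were tested (a mean of at least 5, sums by symbol, detection in all 12 libraries, gerbil symbols) or fewer libraries were used; elsewhere the cause was not tested.

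With a mean of at least 5 the calls were 613 at 4 weeks, 1158 at 16 weeks, 1194 averaged, 125 over time in ND and 914 over time in HFD. Summed by symbol they were 751, 1553, 1623, 86 and 1051, and with gerbil symbols alone 625, 1335, 1408, 123 and 958. Detection in all 12 libraries gave 1908 at 16 weeks, 1950 averaged and 150 over time in ND. Without the HFD libraries numbered 1 the interaction had 455 calls, time in ND 12 and time in HFD 931. The planned 18-library fit called 654 at 4 weeks, 1204 at 8 weeks, 2179 in the interaction, 4401 over time in ND and 4594 over time in HFD. Its interaction and time counts come from F tests that take in the 8-week values, which do not follow the other times. Time in ND also gave 56 with a pseudocount of 0.1, 149 with 5, 14 with no filter and 85 with array weights. At 8 weeks a pseudocount of 5 gave 173.

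With the replicate block time in ND had 19 calls in place of 36 and 8 weeks had 29 in place of 522. ND and HFD libraries of the same number and time had correlations of -0.02 to 0.05 (0 of 9 over 0.1) and the numbers of ND libraries of 4 and 16 weeks 0.04, 0.02 and -0.01, so there the libraries share only a number. For time in HFD, where the numbers were taken as possible pairs, the block gave 1509 in place of the 1610 of the unpaired fit. It changed no other call count by over 1.5 times. Of the 4 splits that part every same-numbered pair, the real one gave 1610 and the highest other 0.

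Lists called at 4 weeks numbered 2, and 1 after median-ratio rescaling, 4 in a separate fit, 0 with an estimated correlation and 7 by fry. Estimated correlation gave 0 at 16 weeks and 0 averaged as well, where camera had 7 and 4 and fry 11 and 11; at an unadjusted p under 0.05 it gave 1 each time. At 8 weeks, where names do not pair with values, camera called 0 of 16 lists (1 at an unadjusted p under 0.05) and fry 1.

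Leaving out 1 library gave 710 to 1194 calls at 4 weeks, 2463 to 3409 at 16 weeks, 2968 to 3595 averaged, 590 to 940 in the interaction, 0 to 233 over time in ND, 981 to 1693 over time in HFD and 56 to 274 at 8 weeks. The lowest were without HFD 4W 3, HFD 16W 2 (16 weeks, averaged, interaction and time in HFD), ND 16W 2 and HFD 8W 1. Lists ranged from 1 to 4 at 4 weeks, 7 to 8 at 16 weeks, 4 to 5 averaged and 0 to 0 at 8 weeks; at 4 weeks 1 was left without ND 4W 2, and 4 were called without HFD 16W 1 or 2.

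Over all alternatives and named genes, 5510 values kept direction and side of the threshold, 240 lost the call, 52 gained it and 17 changed sign, none of the last called. At 4 weeks Fasn went from -0.10 to 0.09 (rescaled), 0.04 (without the HFD libraries numbered 1, and without HFD 4W 1 alone) and 0.03 (HFD 4W 2), with a lowest value of -0.36 (HFD 4W 3), Cat from -0.07 to 0.13 (rescaled) and 0.00 (ND 4W 3), and Glud1 from 0.05 to -0.04 (without the HFD libraries numbered 1, HFD 4W 1 or ND 4W 1) and up to 0.15. Ehhadh went from 0.08 to -0.22 (ND 4W 3) and -0.03 (HFD 4W 2) and up to 0.26, and Hspa8 from 0.04 to -0.24 (ND 4W 3) and -0.15 (HFD 4W 2) and up to 0.32. At 16 weeks Fasn went from 0.09 to -0.38 (ND 16W 3) and -0.04 (HFD 16W 3) and up to 0.35, Afp from -0.09 to a range of -0.21 to 0.29 (highest without HFD 16W 3) and Stab1 from 0.49 to -0.22 (HFD 16W 2) and up to 0.90.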

Other observations

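The tests of explanations in this part were chosen after the result was seen; the splits of libraries were planned, apart from those that move same-numbered libraries together.

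Of the list of fatty acid oxidation, which had too few measured members for a test, Cyp4a10, ACOT1 and Ehhadh fell on HFD at 16 weeks and were not called at 4 weeks. Cyp4a10, a fatty acid hydroxylase, had a log2 fold change of -2.63 (SE 0.54), ACOT1, an acyl-CoA thioesterase, -2.44 (SE 0.23) and Ehhadh, a peroxisomal enzyme, -1.92 (SE 0.47, limma adjusted p = 0.00791). Of 7 genes of fatty acid and triglyceride synthesis, 2 rose and 3 fell at 16 weeks (camera adjusted p = 0.807). Pnpla3, a lipase of lipid droplets, rose by log2 1.34, and Gpam and Dgat1, of triglyceride synthesis, fell, with log2 fold changes of -1.52 and -0.62. Mlxipl, the glucose-sensing factor ChREBP, fell from 30.5 ± 8.43 to 6.90 ± 3.74 at 16 weeks (limma adjusted p = 0.000524) but had been called as higher at 4 weeks (17.6 ± 4.74 in ND and 41.4 ± 1.93 in HFD, log2 1.22, limma adjusted p = 0.0299). The 4-week call was lost without ND 4W 1 (adjusted p = 0.0633), ND 4W 3 (0.11), HFD 4W 1 (0.058), HFD 4W 2 (0.0677) or HFD 4W 3 (0.089), with the replicate block (0.0554) and in the 18-library fit (0.0808).

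All 4 measured heat shock and immediate early genes rose on HFD at 16 weeks. The small heat shock protein HSPB1 rose from 16.5 ± 1.41 to 159 ± 39.7 (log2 3.17, SE 0.24, limma adjusted p = 4.03e-06), Hspa8 by log2 1.48, JUN by 1.43 and Hsp90aa1 by 1.29, the last not called in the 18-library fit (adjusted p = 0.0699). Of 4 measured oxidative stress genes, 3 rose and 1 fell at 16 weeks and 1 rose and 1 fell at 4 weeks, too few for a list test. Hmox1 rose at both times (log2 1.60 and 2.10), and SRXN1, which reduces peroxiredoxins, rose from 6.59 ± 0.955 to 20.9 ± 6.15 at 16 weeks (limma adjusted p = 0.000422) but had a log2 fold change of -0.74 at 4 weeks (adjusted p = 0.0545). Cat, the catalase gene, fell from 647 ± 167 to 305 ± 99.8 at 16 weeks (limma adjusted p = 0.0141), a call lost without ND 16W 1 (0.0502), ND 16W 2 (0.0573) or HFD 16W 1 (0.0577) and in the 18-library fit (0.214). Gpx4, which reduces lipid peroxides, was called as lower at 4 weeks (log2 -0.78, limma adjusted p = 0.0389) and as higher at 16 weeks (0.62, adjusted p = 0.0432). Its 4-week call was lost without ND 4W 1 (0.114) or 3 (0.133), HFD 4W 1 (0.107), 2 (0.0766) or 3 (0.0768) or ND 16W 2 (0.0552), and after rescaling (0.0932). Its 16-week call was lost without ND 4W 1 (0.0537), HFD 4W 2 (0.055) or 3 (0.0544), ND 16W 2 (0.0959) or 3 (0.14), or HFD 16W 1 (0.128) or 2 (0.0829).

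The Clu unigene, ranked 36 to 44 in ND at 4 weeks and 14 to 20 in HFD, ranked 1, 1 and 2 in HFD at 16 weeks, where albumin ranked 2, 3 and 1. In ND at 16 weeks Clu ranked 39, 38 and 11. The values of Clu and ALB at those ranks are fixed by the normalization (28800, 8090 and 5760), so their folds carry ranks and not amounts. Values of the other unigenes are set by rank in the same way, so their folds rest on ranks as well.

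The values of 8 weeks did not follow the unigenes of the other times. A random order of the 8-week values is argued against, because unigenes of the same assembly cluster correlated at 0.26 at 8 weeks (842 pairs; 0.27 at 4 and 0.26 at 16 weeks), above the highest of 1000 random orders (0.12). Other genes being expressed in those livers is argued against by the names of the 200 highest unigenes, of which at most 31% were named at 8 weeks and at least 86.5% at the other times. Values of another assembly, joined to this one by identifier, remain as a candidate explanation, since neighbours in a cluster kept their correlation. No biological explanation was tested beyond the expressed genes.

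The diets ran with 3 library sets. Reads of other organisms, carried by feed, gut or handling, may account for the unigenes seen in 1 set alone, since 76.7% of the named ones seen in ND alone had names outside the gerbil annotation, 28.4% of those in the HFD libraries numbered 1 (Fisher's exact test, p = 0.000267) and 44.2% in the other HFD libraries (p = 1.97e-20), compared with 14.1% of those in all libraries. The calls at 4 weeks were not confined to unigenes missing from some libraries, because 24.49% of the 3377 tested unigenes detected in all 12 libraries were called. This does not decide whether such reads were the whole cause of the calls. Detection in all libraries does not remove them, as the 14.1% shows, and the normalization ranks all unigenes of a library together. Another difference between the sets, such as a day of preparation, and the diet cannot be told apart, because 0 sets hold both diets. An effect of the diet itself on the liver stays open.

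Other splits of the libraries were fitted for each count. For the averaged diet effect 1 of 100 splits, the real one, gave as many calls (3652; highest other 1676), and its 4 called lists were reached by 41 of 100 splits (highest other 9). These splits part HFD libraries of 4 and 16 weeks that share a number and were taken as possible pairs. The splits that move same-numbered libraries together are 10, too few for a share under 0.05; there the real count and the highest other were 3652 and 0 for unigenes and 4 and 5 for lists. For comparisons within 1 time or 1 diet the 10 splits are also too few. There the real count and the highest other were 1149 and 1 at 4 weeks, 522 and 0 at 8 weeks, 3340 and 0 at 16 weeks, 36 and 2 over time in ND and 1610 and 3 over time in HFD. For lists called by camera they were 2 and 3 at 4 weeks, 0 and 0 at 8 weeks (1 list at an unadjusted p under 0.05) and 7 and 8 at 16 weeks. At 4 weeks and at 16 weeks 4 of the 10 splits, the real one included, reached the real count of lists.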
